A study of Gallus gallus with 24 samples.

How the data were processed

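Hypothalamus was taken from 24 Ross broilers on day 42, 6 per group, and sequenced as 1 library per bird. The groups were the basal diet at 24 °C, a diet with 1% L-citrulline at 24 °C, the basal diet at 35 °C and the L-citrulline diet at 35 °C, as given by the labels. Each treatment held 6 replicates of 12 chickens, with 1 bird taken from each, and the temperatures applied from day 28. The labels do not say whether equal replicate numbers in different groups mark a shared cage, chamber or day, and do not give the sex of the birds.

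The deposited expression table holds read counts per gene and FPKM for all 24 libraries, per the file headers. The submitters' processing notes name HISAT2, TopHat, HTSeq and DESeq with genome build GRCg6a, and their versions are not given in the sources used here. Each FPKM value, made by the authors, equals count divided by gene length and column total (largest relative difference 5.2e-15). The deposited DESeq tables of the 6 pairwise comparisons hold log2 fold changes and p-values by the authors, and the deposited enrichment tables hold p-values and false discovery rates for GO terms and KEGG pathways. The counts were used for every test here; the deposited log2 fold changes and p-values are only quoted. The heat map tables, which hold scaled values of genes the authors selected, are not used here. No reference genome was needed, and coordinates are those of the deposited table.

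The table holds 16779 genes, of which 550 have no count in any library and 4303 have no symbol. filterByExpr kept 13742. Libraries held 12635200 to 15001000 counts, 6.50% to 8.19% of them from mitochondrial genes and 7.82% to 12.6% from the 10 most abundant genes. No 2 libraries of a group were copies of one another: the chi-square per degree of freedom between libraries was 7.39 to 91.4 over 60 pairs. In R 4.3.3, counts were scaled by TMM (factors 0.967 to 1.03) and fitted with edgeR 4.0.16 as 4 group means over all 24 libraries, without covariates, with 20 residual degrees of freedom, a biological coefficient of variation of 0.186 and a prior of 3.58 degrees of freedom. Contrasts were tested by the quasi-likelihood F test, with p-values adjusted by the Benjamini-Hochberg method and a threshold of 0.05 without a fold minimum. Standard errors of log2 fold changes are given after ±, and n is 6 per group throughout. The 8 contrasts tested were these: heat on each diet, L-citrulline at each temperature, heat and L-citrulline together, their interaction, and heat and L-citrulline each averaged over the other factor. The precision of a zero was judged by simulation, with 50 genes changed at each fold at the same time in groups of 6. Fewer changed genes would face a stricter adjusted threshold, so a zero in the real data can miss more than these shares say. Of genes given the smallest change (median absolute log2 fold change found 0.28 to 0.34) 18% to 24% were recovered, of those changed 1.5-fold 74% to 80%, of those changed 2-fold 78% to 84%, and of those changed 3-fold 92% to 96%, while 6 to 10 unchanged genes were called. The same scripts, tested on simulated data, called 20 of 20 lists shifted 1.25-fold and 0 of 80 unchanged lists. The simulated genes were drawn independently, so this gives no rate of false list calls for real libraries, whose genes vary together. With the labels of the real libraries permuted, the median number of list calls was 19.

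Gene lists, 29 in all, were fixed before the data were examined, and 28 had at least 5 kept members. They are heat shock proteins and cytosolic chaperones; endoplasmic reticulum chaperones; feeding neuropeptides and receptors; neuroendocrine and stress-axis genes; arginine, citrulline and nitric oxide metabolism. Further lists are circadian clock, immediate early, antioxidant, interferon-stimulated, cholesterol and fatty acid synthesis, thermosensing and prostaglandin, cell cycle, mitochondrially encoded and cytosolic ribosomal protein genes. Cell and tissue lists are microglia and inflammation, lymphocytes, neurons, oligodendrocytes, astrocytes and tanycytes, ciliated ependyma, choroid plexus, endothelium and pericytes, meninges and fibroblasts, erythrocytes, anterior pituitary, hypothalamic region markers, surrounding brain regions (thalamus, telencephalon and optic tectum) and skeletal muscle. The W-linked list kept only 1 symbol and was replaced by the 32 kept genes on chromosome W, used to read the sex of each bird. Lists were tested on log2 CPM with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over 28 lists and the 4 single-factor comparisons (112 tests), and for each other contrast over its 28 lists. Each test was repeated with the correlation estimated from the data and with fry. The level of a list in a library is the mean z-score of its members' log2 CPM (pseudocount 2), compared between groups by exact permutation over 924 splits.

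For each of 6 comparisons (the 4 single-factor and the 2 averaged ones) the text names the 20 genes with the largest change among those that pass and have a mean of at least 1 CPM, 10 in each direction. Where fewer than 10 pass, as here in every comparison, it names the 10 with the smallest p that have a symbol. A fixed set is also reported for the 4 single-factor comparisons, where measured: HSPA8, HSP90AA1, HSPH1, HSPA5, CRH, AVP, POMC, NPY, AGRP, TRH, NOS1, ASS1, ARG2, FOS, PER2, GH, PRL and TTR. HSPA2 and ASL are absent from the table under those symbols, and AGRP and PRL fell below the filter. Members of called lists given as examples were chosen after their values were seen, by small p. Counts of members that pass adjusted over a list alone allow neither for the choice of that list by its result nor for the other genes tested. They are no separate support for a list call.

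Alternatives set in advance were DESeq2 size factors in edgeR, the Wald test of DESeq2 1.42.0, limma voom with sample quality weights, no filter beyond 1 count, a mean of at least 1 CPM, only the 2 groups compared, the replicate number as a block, the W-linked score as a covariate, each library left out in turn, and a rule of unadjusted p under 0.05 with a log2 fold change of at least 1. A pseudocount alternative was not run, since the values are counts. Chosen after seeing the data were leaving out genes on Z and W, and leaving out 3 L-citrulline libraries by no set rule. So was adding scores of 4 tissue lists, with the W-linked score, as covariates. Group labels were also permuted, with 100 groupings per comparison including the real one. The 2401 GO terms of the deposited table that held enough tested genes were tested by camera after the data had been seen.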

Results

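RNA from the hypothalamus of 24 Ross broilers, taken on day 42, was sequenced with 1 library per bird. The 4 groups of 6 birds compared were basal diet at 24 °C, L-citrulline diet at 24 °C, basal diet at 35 °C and L-citrulline diet at 35 °C. The supplement was 1% of the diet, and the 35 °C birds had been in the heat since day 28 at 60% relative humidity. L-citrulline is converted to arginine, the substrate of the nitric oxide synthases. Libraries held 12635200 to 15001000 gene counts, with 14865 to 15054 genes detected in each, and 13742 genes were tested. Across the tested genes the median standard error of a log2 fold change between 2 groups was 0.11, and the biological coefficient of variation was 0.19. In counts simulated at this depth and spread, 74% to 80% of genes made to differ 1.5-fold were recovered. Of those given the smallest change (median absolute log2 fold change found 0.28 to 0.34), 18% to 24% were. There 50 genes were changed at each fold at the same time. Fewer changed genes would face a stricter adjusted threshold, so a zero can miss more than these shares say.

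Genes of the W chromosome, which female chickens carry and males do not, set the libraries apart more than any other genes. Their mean log2 CPM (counts scaled to library size) was 4.04 to 4.30 in 12 libraries and -2.52 to -2.06 in the other 12, with none between. The first principal component held 26.4% of the variance and followed this W-linked score (r = 0.99). High-W libraries numbered 2, 4, 2 and 4 of 6 in the basal 24 °C, L-citrulline 24 °C, basal 35 °C and L-citrulline 35 °C groups. That is 4 of 12 basal birds and 8 of 12 L-citrulline birds (Fisher's exact p = 0.220). The labels do not give the sex of the birds.

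**Figure D1:**
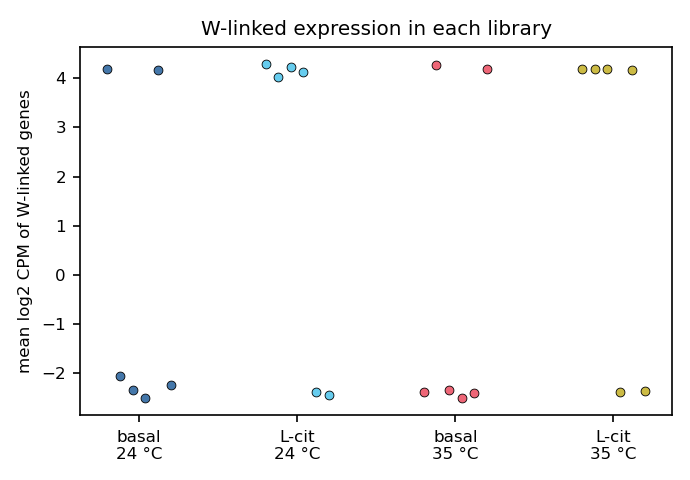
Mean log2 CPM of the 32 tested W-linked genes in each library. High-W libraries number 2, 4, 2 and 4 in the groups from left to right.

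The first question was what 35 °C did in birds on the basal diet. Transcripts of the measured heat shock proteins, the chaperones that refold damaged proteins, differed little in level between 35 °C and 24 °C. HSPA2, another HSP70 gene of the fixed set, had no entry under that symbol, so its response to heat is not known here. HSPA8, the constitutive cytosolic HSP70, had 2848 CPM at 35 °C and 2863 CPM at 24 °C (log2 fold change -0.018 ± 0.072 SE, 95% confidence interval -0.17 to 0.13, n = 6 and 6). HSP90AA1, a cytosolic HSP90, had a log2 fold change of -0.020 ± 0.081, HSPH1, an HSP110 cochaperone, of 0.014 ± 0.12, and HSPA5, the main chaperone of the endoplasmic reticulum, of -0.021 ± 0.10. Of the 26 heat shock and cytosolic chaperone genes, 6 were higher and 20 lower, with a median log2 fold change of -0.030 (adjusted p = 0.193 by camera). The 4 genes with the smallest p values that did not pass were YWHAE, a 14-3-3 adaptor protein (34.1 against 42.5 CPM, log2 fold change -0.33 ± 0.075, 19:5330957-5350899), WDR90 (0.44 ± 0.10), the transcriptional repressor MNT (0.27 ± 0.070) and PLBD2, a lysosomal phospholipase-like protein (0.22 ± 0.059). In all 6 birds at 35 °C, YWHAE was below and MNT above every bird at 24 °C. Genes picked for small p tend to separate the groups, so this adds no evidence, here or in the comparisons below. The next 6, none of them past the test, were RAB11FIP2 (-0.25 ± 0.067), SNRPD2 (-0.37 ± 0.11), BUD13 (0.43 ± 0.12), SCFD2 (-0.25 ± 0.075), the histone acetyltransferase KAT2A (0.20 ± 0.060) and the triglyceride lipase PNPLA2 (-0.31 ± 0.092).

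Among the gene lists, markers of ciliated ependyma, the cells that line the ventricles, rose with heat in basal-diet birds. All 14 were higher, with a median log2 fold change of 0.22 (adjusted p = 1.96e-05 by camera; adjusted p = 0.905 with an estimated correlation). Their largest values were RSPH1 (0.51 ± 0.28) and TEKT2 (0.50 ± 0.20), parts of the ciliary axoneme, and none of the 14 passed adjusted over the list alone. As large a statistic for this list was given by 6 of 100 groupings of the same libraries, the real one included. Basal 35 °C bird 1 stood far above its group in this list. Without it the median was 0.18 (adjusted p = 0.00172 by camera at the preset correlation). The feeding neuropeptide and receptor genes also rose, 19 of 21 being higher with a median of 0.26 (adjusted p = 0.0251; adjusted p = 0.905 with an estimated correlation). Examples are the melanocortin receptor MC4R, which restrains feeding (0.55 ± 0.30), the cholecystokinin receptor CCKBR (0.30 ± 0.13) and TAC1, the precursor of substance P (0.39 ± 0.22), while the appetite-stimulating peptide NPY had -0.28 ± 0.27. Of the 19 transcription factors that mark hypothalamic regions, 18 were higher in the same birds, with a median of 0.24 (adjusted p = 0.196). The feeding call was lost on leaving out any of 4 libraries, with adjusted p = 0.218 at most and a median of 0.16, without basal 24 °C bird 4. For single genes, 0 of 13742 passed at adjusted p under 0.05 in the edgeR quasi-likelihood test, with 507 at unadjusted p under 0.05. DESeq2 and limma voom gave 0 and 0. The nominal expectation for the 507 is 687, but other groupings of the same libraries gave a median of 448, so the nominal value is a poor yardstick here.

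**Figure D2:**
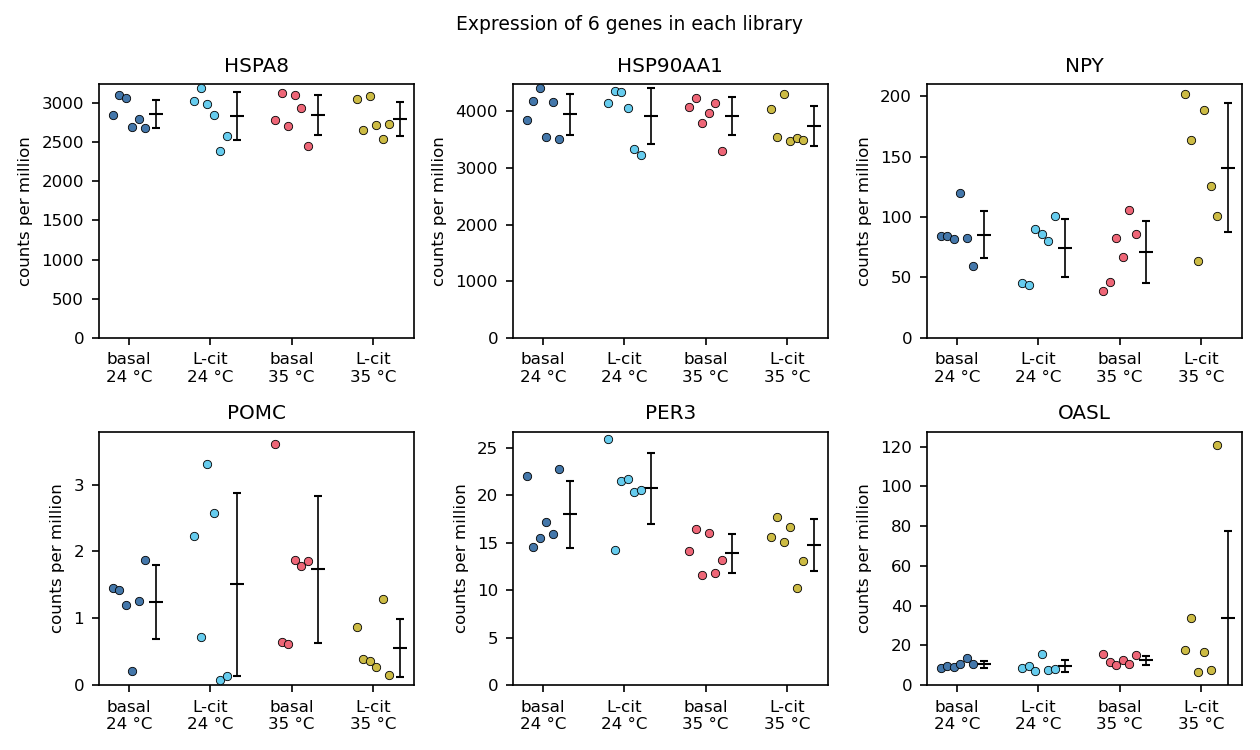
CPM of 6 genes in each library, with the mean and SD of each group. HSPA8 means are 2863, 2837, 2848 and 2796 CPM from left to right, and NPY means are 85.3, 74.1, 70.9 and 140.8 CPM.

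Heat was next compared between birds on the L-citrulline diet. The 10 genes with the smallest p values did not pass in the edgeR test. SLC17A8, the vesicular glutamate transporter VGLUT3, had 1.95 CPM at 35 °C and 5.39 CPM at 24 °C (log2 fold change -1.43 ± 0.30, 1:47293203-47318899), and CHAT, which makes acetylcholine, had a log2 fold change of -2.43 ± 0.60. The calcitonin receptor gene CALCR had -0.73 ± 0.18, the lipid-transfer protein gene ESYT3 -0.78 ± 0.17, VWC2L -0.67 ± 0.15 and FASTKD3 -0.34 ± 0.082. Higher values were those of ALPK3 (0.74 ± 0.16), the clock-linked nuclear receptor RORA (0.54 ± 0.13), MDGA1 (0.34 ± 0.080) and FAM171B (0.20 ± 0.049). NPY had 140.8 CPM at 35 °C and 74.1 CPM at 24 °C (0.95 ± 0.27), POMC, the precursor of the appetite-restraining melanocortins, had -1.41 ± 0.67, and the thyrotropin-releasing hormone gene TRH had -1.12 ± 0.49. None of these 3 passed. POMC was near the floor, at 0.553 CPM at 35 °C and 1.51 CPM at 24 °C, with at most 50 counts in any library. HSPA8 had -0.0024 ± 0.072 and HSP90AA1 -0.048 ± 0.081.

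Interferon-stimulated genes, which encode antiviral proteins, rose with heat on this diet. All 18 were higher, with a median log2 fold change of 0.52 (adjusted p = 9.45e-10 by camera; adjusted p = 0.905 with an estimated correlation). Of the 18, 10 passed adjusted over the list alone, among them OASL (1.86 ± 0.48), MX1 (1.28 ± 0.37), IFI6 (2.06 ± 0.58) and RSAD2 (1.42 ± 0.43). Such an adjustment does not allow for the choice of the list by its result in these same libraries. L-citrulline 35 °C bird 6 had 121 CPM of OASL, against 6.72 to 33.7 CPM in the other 5. Without it the median was 0.25 (17 of 18 higher, adjusted p = 5.29e-04 by camera at the preset correlation), OASL had 0.82 ± 0.29, and 0 of the 18 passed over the list alone. With all birds, 14 of 100 groupings of the same libraries, the real one included, gave as large a list statistic. The microglia and inflammation list had a median of 0.12 in the same comparison (adjusted p = 0.523) and the lymphocyte list 0.24 (adjusted p = 0.591). Ciliated ependyma genes fell here, 14 of 14 being lower with a median of -0.39 (adjusted p = 1.02e-09; adjusted p = 0.438 with an estimated correlation). Of the 14, 6 passed adjusted over the list alone, among them FOXJ1, the master regulator of motile cilia (-0.58 ± 0.18), CFAP44 (-0.74 ± 0.23) and CCDC40 (-0.40 ± 0.13), and 0 without L-citrulline 24 °C bird 5 (median -0.33). The choroid plexus list, also from the ventricles, had a median of -0.37 (adjusted p = 0.328), and its marker TTR had -2.95 ± 1.255, carried by L-citrulline 24 °C birds 1 and 5.

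Cholesterol and fatty acid synthesis genes rose by a small amount in the same comparison, 21 of 22 being higher with a median of 0.14 (adjusted p = 4.42e-04; adjusted p = 0.984 with an estimated correlation), for example ACACA (0.16 ± 0.051) and SC5D (0.16 ± 0.062). The oligodendrocyte list had a median of 0.14 (adjusted p = 0.849). Circadian clock genes rose by a median of 0.094, 13 of 18 being higher (adjusted p = 0.0437; adjusted p = 0.905 with an estimated correlation). Adjusted over the list alone, 3 of them passed: RORA, HLF (0.32 ± 0.11) and, in the other direction, the clock repressor PER3 (-0.47 ± 0.14). The clock call was lost on leaving out any of 9 libraries, with adjusted p = 0.370 at most, without L-citrulline 35 °C bird 3, and with the replicate block (adjusted p = 0.0593). The cholesterol call was lost only without bird 4 (adjusted p = 0.0504), and its median was 0.089 without bird 1. Of 100 groupings of the same libraries, the real one included, 18 gave as large a statistic for the cholesterol list and 9 for the clock list. For single genes, 0 of 13742 passed in the edgeR test, with 922 at unadjusted p under 0.05. DESeq2 called 6 (SLC17A8, ALPK3, VWC2L, ESYT3, ENSGALG00000046384 and ENSGALG00000049439) and limma voom 1 (ENSGALG00000046384).

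**Figure D3:**
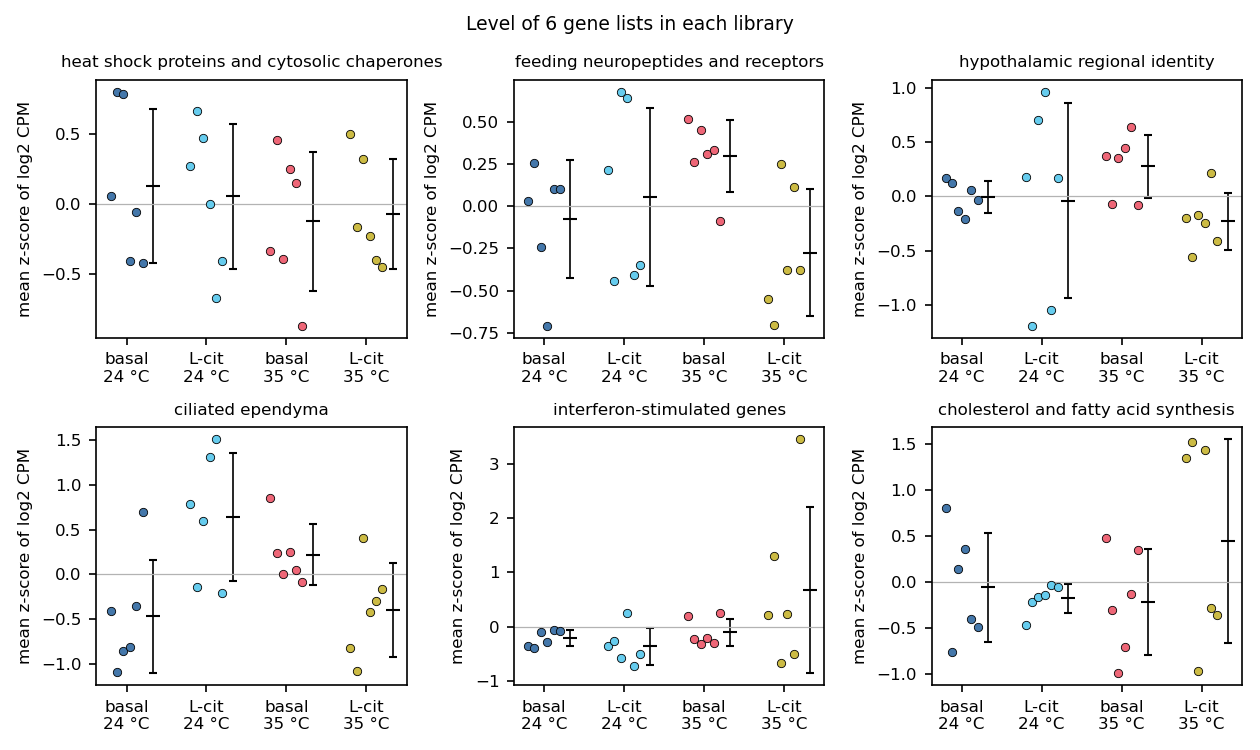
Level of 6 gene lists in each library as the mean z-score of their members, with the mean and SD of each group. The interferon list has a mean of 0.673 ± 1.53 SD in the L-citrulline 35 °C group and of -0.209 ± 0.150 in the basal 24 °C group.

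L-citrulline was then compared with the basal diet at 24 °C. MNT, which opposes MYC at its target genes, came closest to passing of all genes in any comparison: 18.9 against 14.1 CPM, log2 fold change 0.41 ± 0.070, all 6 supplemented birds above every basal bird, adjusted p = 0.0767 by edgeR (19:9522848-9547621). TSPAN33, a tetraspanin, had 0.87 ± 0.18, the splicing factor gene SRSF7 0.18 ± 0.042, and CCKBR 0.54 ± 0.13. FOXJ1 (17.6 against 10.3 CPM, 0.76 ± 0.18) and the dynein assembly factor DAW1 (0.60 ± 0.15) are genes of motile cilia. Lower values were those of MDGA1 (-0.38 ± 0.080), RORA (-0.55 ± 0.13), YWHAE (-0.31 ± 0.075) and ATP5MF, a subunit of the ATP synthase (-0.29 ± 0.073). None of these 10 passed in the edgeR test. This comparison shares a group with each heat comparison, so a gene that differs in the shared group alone appears in both. YWHAE had 42.5 CPM in basal 24 °C birds, against 34.1, 34.5 and 34.5 CPM in the basal 35 °C, L-citrulline 24 °C and L-citrulline 35 °C groups. The nitric oxide synthase gene NOS1 had a log2 fold change of -0.0067 ± 0.24, ASS1, which joins citrulline to aspartate on the way to arginine, had -0.19 ± 0.14, and the arginase gene ARG2 had 0.026 ± 0.089.

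Ciliated ependyma genes rose with the supplement at 24 °C. Of 14, 12 were higher, with a median of 0.46 (adjusted p = 9.45e-10 by camera; adjusted p = 0.438 with an estimated correlation). Of these, 8 passed adjusted over the list alone, among them FOXJ1, HYDIN (0.66 ± 0.17), RSPH1 (0.89 ± 0.28) and CCDC40 (0.46 ± 0.13), and 4 without L-citrulline bird 5. Of 100 groupings of the same libraries, the real one included, 5 gave as large a list statistic. Choroid plexus genes rose as well, 13 of 14 being higher with a median of 0.19 (adjusted p = 0.0404; adjusted p = 0.905 with an estimated correlation), with WFIKKN2 (1.30 ± 0.37) and SLC4A5 (0.68 ± 0.21) passing over the list alone. TTR was 1484 and 2006 CPM in L-citrulline birds 1 and 5 and 1707 CPM in basal bird 6, against 4.23 to 90.6 CPM in the other 9 birds at 24 °C. The choroid plexus call was lost on leaving out any of 7 libraries, with adjusted p = 0.349 at most, without L-citrulline bird 5, and its median was 0.52 without basal bird 6. Its list statistic was reached in 27 of 100 groupings of the same libraries, the real one included. In the edgeR test 0 of 13742 genes passed, with 958 at unadjusted p under 0.05. DESeq2 called 8 (MNT, TSPAN33, MDGA1, SRSF7, ENSGALG00000004946, ENSGALG00000029618, ENSGALG00000042797 and ENSGALG00000049439) and limma voom 1 (MNT).

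At 35 °C the supplement was compared in the same way, with feeding peptides among the genes of smallest p. NPY had 140.8 CPM in L-citrulline birds and 70.9 CPM in basal birds (log2 fold change 1.02 ± 0.28, 2:31464055-31472130), and TAC1 had 51.1 against 92.0 CPM (-0.83 ± 0.22). POMC, at 0.553 against 1.73 CPM, had -1.62 ± 0.66, and AGRP, the other appetite-stimulating peptide of the NPY neurons, was below the count filter with at most 0.757 CPM. ESYT3 had 5.06 against 9.44 CPM (-0.88 ± 0.17, 7:28286840-28313799) and TP53I3, a p53-induced oxidoreductase, 6.88 against 2.71 CPM (1.36 ± 0.31). For these 2 genes, picked for their small p, all 6 supplemented birds lay beyond every basal bird. Other values were MDN1 (0.29 ± 0.074), the retinoid isomerase RPE65 (0.56 ± 0.14), UBTD2 (0.32 ± 0.085), the clathrin adaptor AP2S1 (-0.26 ± 0.069), the monoamine transporter SLC29A4 (-0.37 ± 0.10) and CFAP99 (-0.48 ± 0.13). None of these genes passed in the edgeR test. NOS1 had a log2 fold change of 0.00040 ± 0.24, ASS1 of 0.0078 ± 0.14 and ARG2 of -0.075 ± 0.089.

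Feeding neuropeptide and receptor genes fell with the supplement at 35 °C as a list, 18 of 21 being lower with a median of -0.30 (adjusted p = 4.42e-04 by camera; adjusted p = 0.834 with an estimated correlation). Without L-citrulline 35 °C bird 3 this median was -0.51. Adjusted over the list alone, 2 passed in opposite directions, TAC1 lower and NPY higher, and MC4R (-0.86 ± 0.30) and MC3R (-0.94 ± 0.42) did not. The hypothalamic region markers fell in the same birds, 17 of 19 being lower with a median of -0.50 (adjusted p = 0.00773; adjusted p = 0.905 with an estimated correlation), for example NKX2-1 (-0.84 ± 0.50) and OTP (-0.70 ± 0.37). The list of thalamus, telencephalon and optic tectum markers had a median of -0.029 (adjusted p = 0.950). Ciliated ependyma genes fell, 14 of 14 being lower with a median of -0.21 (adjusted p = 0.00127; adjusted p = 0.905 with an estimated correlation), and none passed over the list alone. Their median was -0.38 without L-citrulline 35 °C bird 3, and the largest adjusted p on leaving out 1 library was 0.0395, without basal 35 °C bird 1.

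Interferon-stimulated genes rose at 35 °C with the supplement, 18 of 18 being higher with a median of 0.49 (adjusted p = 1.40e-05; adjusted p = 0.926 with an estimated correlation). Of these 18, 6 passed adjusted over the list alone, among them OASL (1.45 ± 0.47), MX1 (1.02 ± 0.36) and TRIM25 (0.70 ± 0.25), beside a microglia list median of 0.13 (adjusted p = 0.107) and a lymphocyte list median of 0.38 (adjusted p = 0.355). This call was lost only without L-citrulline bird 6 (adjusted p = 0.343, median 0.13), when OASL had 0.41 ± 0.29 and 0 of the 18 passed over the list alone. Cholesterol and fatty acid synthesis genes rose, 20 of 22 being higher with a median of 0.16 (adjusted p = 2.09e-04; adjusted p = 0.970 with an estimated correlation), with SC5D (0.22 ± 0.063) passing over the list alone. As large a statistic for the cholesterol list came from 25 of 100 groupings of the same libraries, the real one included. Genes of oligodendrocytes, the cells that make cholesterol-rich myelin, had 13 of 14 higher with a median of 0.29 (adjusted p = 0.0632). In the edgeR test 0 of 13742 genes passed, with 884 at unadjusted p under 0.05. DESeq2 called 1 (ESYT3) and limma voom 0. Without 3 L-citrulline libraries, chosen after the values were seen and by no set rule, the edgeR count was 12, among them CAMK1G, PPIF and UTRN. Regroupings were not run under this exclusion, so chance is not excluded for that count.

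Heat and L-citrulline together were compared with the basal diet at 24 °C. Interferon-stimulated genes were higher in 18 of 18, with a median of 0.55 (adjusted p = 1.11e-08; adjusted p = 0.494 with an estimated correlation). Adjusted over the list alone, 9 of the 18 passed, among them OASL, MX1, IFI6 and IRF7. L-citrulline 35 °C bird 6 had the highest OASL (121 CPM) and IFI6 (40.0 CPM, against 0.657 to 9.81 CPM in the other 5 of its group). Without that bird the list call held at adjusted p = 0.0243 by camera at the preset correlation, with a median of 0.17. OASL went from 1.72 ± 0.48 to 0.68 ± 0.29, and 0 of the 18 passed over the list alone. With all birds, 22 of 100 groupings of the same libraries, the real one included, gave as large a list statistic. In the same comparison the lymphocyte list had a median of 0.32 (adjusted p = 0.201) and the microglia list 0.12 (adjusted p = 0.239). Cholesterol synthesis genes had a median of 0.12 (20 of 22 higher; adjusted p = 0.00380; adjusted p = 0.776 with an estimated correlation), beside an oligodendrocyte list median of 0.20 (14 of 14 higher; adjusted p = 0.201). The neuroendocrine and stress-axis list had a median of -0.16 (18 of 24 lower; adjusted p = 0.0460; adjusted p = 0.494 with an estimated correlation), and the cytosolic ribosomal proteins -0.015 (45 of 68 lower; adjusted p = 0.0460; adjusted p = 0.776 with an estimated correlation). These 3 calls were lost on leaving out any of 4, 10 and 8 libraries (adjusted p = 0.261, 0.218 and 0.861 at most), with medians of 0.076 to 0.19 for cholesterol synthesis, -0.23 to -0.078 for the neuroendocrine list and -0.044 to 0.013 for the ribosomal proteins. Of 100 groupings of these libraries, the real one included, 33 gave as large a statistic for the cholesterol list and 10 for the neuroendocrine list. In the edgeR test 0 of 13742 genes passed, with 533 at unadjusted p under 0.05, and DESeq2 and limma voom gave 0 and 0.

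Whether heat acted differently on the 2 diets was tested by the interaction. Ciliated ependyma genes gave the clearest difference: all 14 had a lower heat effect on the L-citrulline diet, with a median of -0.67 (adjusted p = 3.28e-12 by camera; adjusted p = 0.102 with an estimated correlation; adjusted p = 0.0371 by fry). Adjusted over the list alone, 10 of the 14 passed, among them RSPH1 (-1.30 ± 0.39), FOXJ1 (-0.80 ± 0.26) and HYDIN (-0.66 ± 0.24), and 0 without L-citrulline 24 °C bird 5 (median -0.56). That count does not allow for the choice of this list by its size. Over all 13742 genes the smallest adjusted p of the edgeR interaction test was 0.241. The feeding list had a median of -0.57 (adjusted p = 0.00318; adjusted p = 0.7002 with an estimated correlation), with TAC1, MC4R and CCKBR lower and NPY higher over the list alone, beside -0.76 for the hypothalamic region markers (16 of 19 lower; adjusted p = 0.167). The interferon list had 0.52 (adjusted p = 2.97e-04; adjusted p = 0.986 with an estimated correlation) and the cholesterol list 0.19 (adjusted p = 0.00208; adjusted p = 0.986 with an estimated correlation), beside 0.20 for oligodendrocytes (adjusted p = 0.623) and -0.21 for choroid plexus (adjusted p = 0.403). The interferon difference was lost only without L-citrulline 35 °C bird 6 (adjusted p = 0.141, median 0.19), and the microglia and lymphocyte lists had 0.16 (adjusted p = 0.399) and 0.042 (adjusted p = 0.799). Across all 13742 genes the heat effects of the 2 diets, which share no libraries, had a correlation of r = -0.170 (jackknife SE 0.159) and the same sign in 41.9% of genes. The 2 L-citrulline effects had r = 0.0059, and r = -0.0710 without genes on Z and W. Effects that share a group were correlated through its birds, so they are not separate results. With L-citrulline at 24 °C, heat had r = 0.469 on the basal diet and -0.607 on the L-citrulline diet. With L-citrulline at 35 °C, heat had r = -0.520 on the basal diet and 0.553 on the L-citrulline diet. In the edgeR test of the interaction 0 genes passed, with 1039 at unadjusted p under 0.05. DESeq2 called 2 (ENSGALG00000009552 and ENSGALG00000029618) and limma voom 0.

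Averaged over both diets, the gene with the smallest p for heat was PER3, a repressor of the circadian clock, at 13.9 and 14.7 CPM in the heated groups and 17.97 and 20.71 CPM in the others (log2 fold change -0.43 ± 0.10, 21:291189-310409). PER2, its paralog, had -0.037 ± 0.11. HERPUD1, which clears misfolded proteins from the endoplasmic reticulum, had -0.30 ± 0.081, UNC13D 0.39 ± 0.11, TAPBPL, which edits peptides on MHC class I, 0.38 ± 0.11, THEM4 0.21 ± 0.055, MED12L 0.20 ± 0.059, CLVS1 0.17 ± 0.046, C25H1ORF43 0.12 ± 0.035, CDC73 -0.10 ± 0.031 and SLC17A8 -0.70 ± 0.21. The choroid plexus gene TTR had -2.87 ± 0.89, carried by 3 birds at 24 °C with 1484 to 2006 CPM, the other 21 birds of the study having 4.23 to 165 CPM. None of these genes passed. Interferon-stimulated genes were higher in 18 of 18 with a median of 0.34 (adjusted p = 1.09e-08; adjusted p = 0.838 with an estimated correlation). Without L-citrulline 35 °C bird 6 this median was 0.14 (adjusted p = 2.43e-04 by camera at the preset correlation), and on the basal diet alone it was 0.064 (adjusted p = 0.713). The lymphocyte list had 0.11 (adjusted p = 0.489) and the microglia list 0.0095 (adjusted p = 0.783). In the edgeR test 0 genes passed, with 416 at unadjusted p under 0.05, and DESeq2 and limma voom gave 0 and 0.

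Averaged over temperatures, the 10 genes with the smallest p for L-citrulline were led by CD40, a costimulatory receptor of immune cells, at 5.15 and 5.54 CPM with the supplement and 3.62 and 3.79 CPM without (log2 fold change 0.53 ± 0.12, 20:10622623-10626251). RPE65 had 0.39 ± 0.10, FAM135B 0.40 ± 0.11, WDHD1, a replication factor, 0.46 ± 0.12, the helicase RECQL5 0.21 ± 0.055, NBEAL1 0.21 ± 0.057 and ERLIN1, which restrains cholesterol synthesis, 0.15 ± 0.043. AP2S1 had -0.20 ± 0.049, the clock repressor CRY1 -0.17 ± 0.045 and ESYT3 -0.45 ± 0.12. None of these passed, and no gene list was called. Of the 753 genes at unadjusted p under 0.05, 80 (10.6%) lie on the Z or W chromosome, against 4.80% of the genes tested. With the W-linked score as a covariate these were 36 of 993. In the edgeR test 0 genes passed, and DESeq2 and limma voom gave 0 and 0. Since the edgeR test called no gene in any comparison, it gave no overlap between comparisons to count. DESeq2 called ESYT3, ENSGALG00000049439 and ENSGALG00000029618 in 2 comparisons each, which in every case share libraries.

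The remaining genes of a set fixed in advance were also compared, and none passed in the edgeR test. For heat on the basal diet FOS, an immediate early gene, had -0.16 ± 0.17, the stress-axis genes CRH and AVP -0.078 ± 0.37 and 0.49 ± 0.48, TRH 0.46 ± 0.48, POMC 0.48 ± 0.61, GH 0.016 ± 0.23, PER2 0.0026 ± 0.15, NOS1 -0.014 ± 0.24, ASS1 0.047 ± 0.14 and ARG2 0.0046 ± 0.089. TTR had -2.79 ± 1.26 there, and 0.61 ± 0.99 without basal 24 °C bird 6. For heat on the L-citrulline diet FOS had 0.34 ± 0.17, CRH -0.19 ± 0.37, AVP -0.42 ± 0.48, GH -0.26 ± 0.23, PER2 -0.076 ± 0.15, HSPH1 0.0071 ± 0.12, HSPA5 -0.020 ± 0.10, NOS1 -0.0068 ± 0.24, ASS1 0.24 ± 0.14 and ARG2 -0.096 ± 0.089. This ASS1 value, like that for L-citrulline at 35 °C, includes L-citrulline 35 °C bird 6, at 6.44 log2 CPM against 5.84 to 5.94 in the rest of its group. For L-citrulline at 24 °C FOS had -0.33 ± 0.17, CRH -0.29 ± 0.37, AVP 0.39 ± 0.48, TRH 0.74 ± 0.48, POMC 0.27 ± 0.61, NPY -0.21 ± 0.27, GH 0.41 ± 0.23, PER2 0.16 ± 0.15, HSPA8 -0.022 ± 0.072, HSP90AA1 -0.021 ± 0.081, HSPH1 -0.088 ± 0.12, HSPA5 0.052 ± 0.10 and TTR 0.96 ± 1.17. At 35 °C the supplement gave FOS 0.18 ± 0.17, CRH -0.40 ± 0.37, AVP -0.53 ± 0.48, TRH -0.85 ± 0.49, GH 0.14 ± 0.23, PER2 0.086 ± 0.15, HSPA8 -0.0062 ± 0.072, HSP90AA1 -0.048 ± 0.081, HSPH1 -0.094 ± 0.12, HSPA5 0.053 ± 0.10 and TTR 0.81 ± 1.20.

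Of the 28 lists tested, 21 were called in none of the 4 single-factor comparisons. The arginine, citrulline and nitric oxide list, 24 genes, had medians of -0.019 to 0.021 (smallest adjusted p = 0.698). The medians and smallest adjusted p of the other stress and signalling lists were -0.025 to 0.046 and 0.584 for endoplasmic reticulum chaperones, -0.28 to 0.092 and 0.182 for neuroendocrine genes, -0.056 to 0.17 and 0.123 for immediate early genes, -0.030 to 0.038 and 0.591 for antioxidant genes, -0.032 to 0.010 and 0.666 for thermosensing channels and prostaglandin signalling, and -0.029 to 0.043 and 0.591 for cell cycle genes. For cell types they were -0.030 to 0.025 and 0.468 for neurons, -0.064 to 0.071 and 0.193 for astrocytes and tanycytes, -0.022 to 0.056 and 0.523 for endothelium and pericytes, and -0.13 to 0.45 and 0.141 for meninges and fibroblasts. For erythrocytes they were -0.25 to 0.59 and 0.523, for anterior pituitary -0.080 to 0.00074 and 0.591, for skeletal muscle -0.27 to 0.15 and 0.591, for surrounding brain regions -0.18 to 0.29 and 0.328, for mitochondrially encoded genes -0.013 to 0.054 and 0.758, and for cytosolic ribosomal proteins -0.023 to 0.0080 and 0.0771. The median, the mean and the test differed in sign in 29 of the 112 tests, and in 0 of the 13 that were called. When the levels of the lists per library were compared by exact permutation, 0 of 112 passed after adjustment (smallest adjusted p = 0.485).

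The deposited DESeq tables of the study hold 1 gene at adjusted p under 0.05 in the comparison of L-citrulline with basal diet at 35 °C, TP53I3 (log2 fold change 1.37, adjusted p = 8.36e-04), and 0 in the other 5 pairwise comparisons. For NPY in that table the log2 fold change is 1.02 and for POMC -1.62. At unadjusted p under 0.05 and an absolute log2 fold change over 1, the tables hold 57 genes for L-citrulline at 24 °C (42 higher) and 38 for L-citrulline at 35 °C (23 higher). They hold 27 for heat on the basal diet (17 higher), 53 for heat on the L-citrulline diet (11 higher) and 31 for heat and L-citrulline together (20 higher). In the deposited enrichment table for L-citrulline at 35 °C the first term is neuropeptide receptor binding (FDR 6.3e-07), from genes chosen on these same samples.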

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

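The tests that leave out 1 bird, and the comparison with the most extreme of all lists, were chosen only after the result was seen. Libraries far from the other 5 of their group were sought among 376 groups of 6 (112 for lists and 264 for named genes), by the gap to the nearest library relative to the range. Of these, 24 had such a library, where chance gives about 1 in 20 groups.

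For list levels (mean z-score) these were lymphocytes at 0.760 in L-citrulline 35 °C bird 2, and thermosensing genes at -0.311 in basal 35 °C bird 6 and 0.281 in L-citrulline 35 °C bird 3. Ciliated ependyma stood at 0.857 in basal 35 °C bird 1, choroid plexus at 0.794 in basal 24 °C bird 6, and cell cycle at -0.751 in basal 24 °C bird 2. Meninges and fibroblasts stood at 0.715 in basal 24 °C bird 3, 2.08 in L-citrulline 24 °C bird 5 and 0.396 in basal 35 °C bird 3. For genes (log2 CPM) they were in L-citrulline 24 °C birds RPE65 at 3.49 (bird 1), THEM4 at 4.04 and CRY1 at 6.44 (bird 4), PLBD2 at 6.52 and CLVS1 at 5.12 (bird 5) and CDC73 at 5.59 (bird 6). In basal 24 °C birds they were SRSF7 at 6.21 (bird 1), POMC at -1.47 (bird 4), HERPUD1 at 4.16 (bird 5) and CD40 at 1.30 (bird 6). In basal 35 °C birds they were ERLIN1 at 5.08 (bird 4) and WDHD1 at 1.35 (bird 5), and in L-citrulline 35 °C birds FASTKD3 at 3.25 (bird 2), HSPH1 at 8.36 (bird 3) and ASS1 at 6.44 (bird 6).

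Heat effects differed between the diets, by the test of the interaction, for 4 lists: ciliated ependyma (median log2 difference -0.67), feeding neuropeptides (-0.57), interferon-stimulated genes (0.52) and cholesterol synthesis (0.19). These calls are at the preset correlation, and with an estimated one none passed (adjusted p = 0.102, 0.7002, 0.986 and 0.986).

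Ciliated ependyma genes had opposite heat effects on the 2 diets, which may reflect how much ventricle wall each tissue piece held. With the choroid plexus and tanycyte scores as covariates the interaction of the list score was -1.52 ± 0.41 SE against -1.73 ± 0.47 without them, so those scores account for little of it, and without L-citrulline 24 °C bird 5 it was -1.55 ± 0.46. Of 100 permutations of the labels only 1, the real one, gave a list statistic as large (absolute log10 p 12.9, highest other 8.54), but some list of the 28 was as extreme in 13 of 100 groupings (highest other 26.6), and this list was picked for its size. Within groups the ependyma score had r = 0.538 with choroid plexus (adjusted permutation p = 0.0575, Spearman rho 0.342; r = 0.173 without the 2 libraries that carry it) and r = 0.0097 with tanycytes, so neither relation passed. In the single comparisons, 6 and 2 of 100 groupings gave as large an ependyma statistic for heat on the basal and the L-citrulline diet. For L-citrulline they were 5 at 24 °C and 1 at 35 °C, the real grouping included. These counts do not allow for the choice among 28 lists. Ependyma without choroid plexus in the piece stays open, as does an effect of diet and temperature.

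Interferon-stimulated genes were higher in the heated L-citrulline birds, which 1 bird could account for in the comparison with heated basal birds. Without bird 6 the list score differed by 0.217 ± 0.257 SE, against 0.774 ± 0.460 with it, and 32 of 100 groupings of the 12 heated libraries gave a list statistic as large (real 6.30, highest other 18.6), so chance is not excluded. With lymphocyte and microglia scores as covariates the difference was 0.575 ± 0.479, which leaves immune cells in the tissue open. An infection of that bird was not tested.

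Feeding neuropeptide genes were lower and NPY higher in the heated L-citrulline birds, and the first may come from less hypothalamus in the piece. With the hypothalamic identity score as a covariate the list without NPY differed by -0.382 ± 0.191 SE, against -0.679 ± 0.241 without it, and within groups the 2 scores followed each other (r = 0.745, adjusted permutation p = 0.00154), so tissue content and diet cannot be told apart for this part. For NPY the difference was 0.867 ± 0.210 with hypothalamic and surrounding-tissue scores as covariates and 0.990 ± 0.306 without, so those scores account for little of it. Each score is a mean over markers of several regions, so tissue that neither follows stays open as a source of NPY. Of 100 groupings of the heated libraries only the real 1 gave as large a list statistic (4.50, highest other 4.14), but some list of the 28 reached that value in 92 of 100. A diet effect on NPY is therefore a hypothesis, for a gene that did not pass in the test of all genes.

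Counts of genes at unadjusted p under 0.05 were compared with 100 groupings of the same libraries, the real one included, and chance was not excluded for any. As many genes were given by 33 for heat on the basal diet (real 507, highest other 1005), 38 for heat on the L-citrulline diet (922, 2299), 9 for L-citrulline at 24 °C (958, 1481) and 20 at 35 °C (884, 2286). They were 56 for heat and L-citrulline together (533, 2857), 8 for the interaction (1039, 1686), 82 for heat averaged (416, 1986) and 29 for L-citrulline averaged (753, 2495). For the 13 list calls, 89 of 100 permutations gave as many, with a median of 19 and a highest of 34, so the list calls at the preset correlation are not beyond what chance gives in these libraries. For heat and L-citrulline together 2 regroupings called 555 and 172 genes, and what those regroupings separate was not tested.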

How the results depend on the processing

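Leaving out 3 libraries and leaving out genes on Z and W were chosen only after the result was seen, as were the tissue scores and the alternatives for lists other than the block, the estimated correlation and fry. With DESeq2 the counts of genes were 6 for heat on the L-citrulline diet, 8 for L-citrulline at 24 °C, 1 at 35 °C, 2 for the interaction and 0 for the other 4. With limma voom they were 1, 1 and 0 for the first 3 of these, and 0 elsewhere. Size factors, no filter, a mean of at least 1 CPM, only the groups compared, the W-linked score, genes on Z and W left out and the tissue scores gave 0 in each comparison they were run for. The tissue scores, fitted with the W-linked score, changed the counts at unadjusted p under 0.05. L-citrulline at 24 °C (958 to 567), at 35 °C (884 to 690) and averaged (753 to 567) fell. So did heat on the L-citrulline diet (922 to 676) and the interaction (1039 to 696). Heat on the basal diet (507 to 616), both together (533 to 589) and heat averaged (416 to 567) rose. For L-citrulline at 24 °C the smallest adjusted p by edgeR was 0.992, against 0.0767. At unadjusted p under 0.05 with a log2 fold change of at least 1 the counts were 24 and 76 for heat on the basal and the L-citrulline diet, 56 and 50 for L-citrulline at 24 and 35 °C, 28 for them together, 161 for the interaction, and 14 and 13 averaged. Without 3 L-citrulline libraries (24 °C bird 5 and 35 °C birds 3 and 6) 2 genes passed in edgeR for heat on the L-citrulline diet. For L-citrulline at 35 °C 12 passed (CAMK1G, ZNF385C, ALAS2, TAOK1, PPIF, LY75, UTRN, PGM2L1, CELF5, CPNE4, TMEM158 and ENSGALG00000027514). These 3 were picked by no set rule. The limma voom quality weight of 35 °C bird 6 was 0.771, above those of L-citrulline 24 °C birds 2 (0.694) and 6 (0.702), which were kept. The cause was not tested.

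Leaving out 1 library at a time gave 0 to 1 genes for heat on the L-citrulline diet and for L-citrulline at 24 °C and 0 to 0 for the other 6. MNT was called without basal 24 °C bird 3 or L-citrulline 24 °C bird 2. The list calls ranged from 10 to 21 and the correlation of the heat effects from -0.239 to -0.0964. Under the other alternatives this correlation was -0.0787 with no filter, -0.0807 with DESeq2 and -0.258 with the tissue scores, and the rest lay between. The list calls were 0 with an estimated correlation, 0 with fry, 16 with the W-linked score and 19 without the 3 libraries. Of 930 values of named genes under 6 alternatives, 911 kept their direction and side of the threshold, 9 passed under DESeq2 and 10 changed sign, mostly near 0. NOS1 at 35 °C went to -0.0020 with no filter, -0.0076 at 1 CPM, -0.0052 with the block and -0.092 with the W-linked score. Also with the block, GH (-0.0013) and PER2 (-0.011) changed sign for heat on the basal diet, HSPA8 (0.0026) for heat on the L-citrulline diet and ASS1 (-0.0027) for L-citrulline at 35 °C. HSPH1 for heat on the L-citrulline diet went to -0.0020 at 1 CPM, and POMC for L-citrulline at 24 °C to -0.21 with the W-linked score. The cause was not tested.

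The replicate number did not pair the libraries: 36 same-number pairs had a mean correlation of 0.0054, and 5 of 24 libraries correlated best with their own number. With that number as a block the counts of genes were 0 in all 8 comparisons and the list calls 13, of which 12 were also called without it.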

Other observations

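The GO terms and the correlations between list scores below were chosen only after the result was seen. Tested by camera on 2401 GO terms, genes of cilia gave the lowest p values for heat on the L-citrulline diet and for the interaction. Axoneme assembly (13 genes) had a median log2 fold change of 0.34 for L-citrulline at 24 °C (adjusted p = 4.36e-04) and -0.31 for heat on the L-citrulline diet (adjusted p = 1.32e-06), and motile cilium assembly (16 genes) had -0.25 for the latter (adjusted p = 1.32e-06). Terms of the respiratory chain and ATP synthase were all 4 of the calls for heat on the basal diet, each lower. Of them complex I (39 genes) had -0.068 there (adjusted p = 0.0131), and it had the lowest p for L-citrulline at 24 °C (-0.099, adjusted p = 1.48e-05), where 10 of 16 called terms were lower. L-citrulline at 24 °C shares a group with each heat comparison, so the paired values of complex I and of axoneme assembly are not separate results. Neuropeptide signaling (67 genes) had -0.22 for L-citrulline at 35 °C (adjusted p = 0.00660). For L-citrulline averaged over temperatures, chemical synaptic transmission (108 genes) had -0.049 and collagen trimer (31 genes) 0.15 (adjusted p = 0.0392 each). With an estimated correlation 0 terms passed in any comparison.

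Myelin and choroid plexus transcripts varied widely between birds of a group. MBP, the myelin basic protein gene, ranged from 7581 to 30130 CPM and TTR, the transthyretin of the choroid plexus, from 4.23 to 2006 CPM over the 24 libraries. Within groups the cholesterol synthesis score followed the oligodendrocyte score (r = 0.731, adjusted permutation p = 0.00417), and the interferon score had r = 0.456 with microglia and 0.131 with lymphocytes. The hypothalamic identity score had r = 0.033 with the oligodendrocyte score. The vasopressin homolog gene AVP was the most abundant of the neuroendocrine genes named, at 2511, 3296, 3548 and 2414 CPM in the 4 groups, and CRH had 30.2, 24.9, 28.8 and 21.7 CPM.

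The quality weights of limma voom were lowest for L-citrulline 35 °C bird 3 (0.361). The correlation of the heat effects of the 2 diets across genes, r = -0.170, was as low in 8 of 100 permutations of the labels, the real one included, whose other values ranged from -0.279 to 0.258.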
